A study of Mus musculus with 45 samples.

How the data were processed

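Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on mouse liver, per the labels. The series holds 45 samples in 18 groups, and the lists analysed here come from 8 of them in 2 groups: livers of mice whose endogenous REV-ERBα carries a 3HA epitope tag, immunoprecipitated with anti-HA beads, with 4 samples at zeitgeber time 10 (ZT10) and 4 at ZT22. Nuclei were fixed with formaldehyde and EGS, a longer protein crosslinker, chromatin was sonicated, and libraries were made by Tn5 tagmentation, per the labels' protocols. The other 37 samples (histone marks, NCOR1, input, anti-HA on untagged liver and livers given AAV vectors) were not analysed here.

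The deposited data are 1 peak list per time, and the authors pooled the 4 samples of a time before they made it, per the labels. The submitters' processing notes name bcl2fastq 2.17, cutadapt 2.3, BWA 0.7.17, Picard 2.18.12, SAMtools 1.9, MACS2 2.1.2 and deepTools 3.3.0 and the mouse build mm10, with no role or order for any of them. Which library served as the control is not given in the sources used here. Each peak has a start, an end and a summit. The fold enrichment in the deposited lists is the ratio of the summit to the local background, the peak's own value as the authors gave it. The lists also hold a −log10 p and a −log10 q per peak from the authors' peak caller. The score column in the deposited lists is 10 times the −log10 q, without its decimals, and it was not used. Folds were used to describe and rank peaks within a list. No peak in either list has a fold below 4. Peak numbers ran to 50041 at ZT10 and to 78 at ZT22, so 22112 and 42 numbers have no peak in the lists. At ZT10 the levels of 81 and 82 fragments, with folds of 3.92 and 3.96, held 0 peaks, and those of 83 and 84 fragments held 342 and 362.

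Depth was worked out from the lists, since they hold no read totals. Pileup and local background at each summit were solved from the fold and the −log10 p of the same peak, with a pseudocount of 1 in the fold and the Poisson upper tail of the whole part of the pileup. The lowest background, 4.14, was found from the ZT10 list and used for both lists, and 72.2% of ZT22 peaks fitted it. Summits lay within 0.1 of a whole number of fragments at 99.2% of ZT10 and 97.2% of ZT22 peaks, where 20% would by chance. From the worth of 1 fragment, the ZT22 pool had 0.97 times the depth of the ZT10 pool, if the same control served both. Summits held 83 to 3378 fragments at ZT10 (median 149) and 82 to 3656 at ZT22 (median 133.5). Intervals from these counts cover counting error only.

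Genes and their coordinates came from a RefSeq table of GRCm38.p6, whose coordinates are those of mm10. It gives no strand, no exons and no starts inside a gene span, and no genome sequence was used here. The planned distance to the 5′ end of a gene was therefore replaced by the distance to the nearer of its ends, and peaks are placed inside or outside gene spans only. The planned tests of DNA motifs, of half-site spacing and of motifs by peak strength were not run, nor was the alternative without repeats. The gene background was 21627 protein-coding genes on chromosomes 1 to 19 and X. All 382 entries of the 24 gene lists matched it.

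Peaks were called shared with at least 1 bp of overlap. The number expected by chance came from 10000 random placements of the ZT22 peaks on their chromosomes, and a share has an exact Clopper-Pearson interval at 95%. Mean log2 folds were compared with two-sided permutation tests of 100000 resamples, for which 1e-05 is the smallest p. Distances of summits were set against 100000 random positions. For each list, members with a summit within 10 kb of either end were compared with all other genes by Fisher's exact test, two-sided. The mean rank of each member's strongest fold was compared with 100000 random lists of the same size, genes with no summit sharing the lowest rank. Both were adjusted by the Benjamini-Hochberg method over the 24 lists, with a threshold of 0.05. With 1 pooled list per time there is no spread between replicates, so no p-value was computed between the times, and p-values here compare peaks or genes within 1 list. Ratios of fragment counts between the times, given in the closing observations, have intervals that leave out replicate spread.

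The lists, the tests and the rule for named genes were fixed before the data were examined. The rule takes every core clock gene, the genes nearest the 15 ZT10 peaks of highest fold, the genes nearest the 10 ZT22 peaks of highest fold, and the 3 members of each other list with the strongest summit. Members with no summit are named where 5 or fewer of a list lack one. Not every gene the rule takes is reported here. The alternatives were a −log10 q of at least 5 or 10 in the ZT10 list, 1 row per interval, other overlaps (50% of each peak, or summits within 100 bp), reaches of 2 and 50 kb, the nearest gene only, neighbouring members counted once, strength as −log10 q, ends of all annotated genes and a pseudocount of 0. Alternatives chosen after seeing the data were length-matched random genes (10 length classes), the gene span, leaving out the X chromosome, a −log10 q of at least 5 or 10 in the ZT22 list or in both lists, strength among genes with a summit only, and leaving out ZT22 peaks with a local background over 2 times the lowest.

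The statistics named in this paragraph were tested on simulated data. Random placements, distance shares and the tests of common loss, the X chromosome and neighbouring peaks were not. Of 20 planted overlaps 20 were found, and of 1932 simulated summits 99.8% were recovered within 0.1 fragment. Of lists with planted members, 64% were called by the gene list test and 4.5% of random lists were. Of lists with members from the strongest genes, 100% were called by the strength test, and 4.5% of random ones. The comparison of means called 100% of shifted and 5% of unshifted sets. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.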

Results

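The binding of REV-ERBα, a nuclear receptor that represses transcription in the circadian clock, was mapped in mouse liver at ZT10 and ZT22, hours 10 and 22 of the light-dark cycle. Each time has 1 list of peaks from 4 pooled samples, so values have no replicate spread and no p-value was computed between the times. The ZT10 list held 27929 peaks that covered 64.4 Mb, with a median width of 1679 bp and a median fold of 6.81 over the local background. The ZT22 list held 36 peaks that covered 45.5 kb, with a median width of 504.5 bp and a median fold of 5.96. The pools had about equal depth, at 0.97 for ZT22 relative to ZT10, if the same control served both.

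The first comparison asks whether the sites occupied at ZT22 are those occupied at ZT10. The 3 sites of highest fold were the same at both times, and whether their signal depends on the tag was not tested, since untagged liver was not analysed here. The strongest ZT10 peak, with a fold of 152.7, lay on chromosome 11 from 44167577 to 44176973, outside any gene and 226720 bp from Il12b, which encodes an interleukin subunit. The ZT22 peak there had a fold of 57.5 and was the strongest of its list. The next sites in both lists lay in 1700010I14Rik on chromosome 17, with folds of 103 at ZT10 and 41.3 at ZT22, and in Loxl4, a lysyl oxidase gene on chromosome 19, with folds of 101.99 and 35.3. At Npas2, which encodes a partner of BMAL1, a peak whose summit lay 774 bp outside the gene had a fold of 77.7 at ZT10, and the ZT22 peak there had a fold of 7.17.

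Of the 36 ZT22 peaks, 30 were overlapped by a ZT10 peak (83.3%, 95% interval 67.2 to 93.6, exact Clopper-Pearson). Random placement gave 1.66 on average and at most 8 in 10000 placements. These 30 fell on 24 ZT10 peaks, which is 0.0859% of that list. Some ZT22 peaks thus lay side by side under the same ZT10 peak, while the interval and the placements treat them as independent. The 24 had a mean log2 fold at ZT10 of 5.14 ± 1.21 (SD), against 2.92 ± 0.71 for the other 27905, a difference of 2.22 (permutation p = 1e-05, the smallest possible). They included 6 of the 15 and 14 of the 100 ZT10 peaks of highest fold. The other ZT22 peaks among the 10 of highest fold lay 366777 bp from Zdhhc25 (29.9), in Ppp2r5c (10.0), in Dop1b (9.43), a further one in 1700010I14Rik (9.15), 17262 bp from Sbk1 (8.20) and 26301 bp from Adra1b (7.87), with the ZT22 fold in parentheses. Of these, the peak in Dop1b had no ZT10 peak over it. When shared meant that at least 50% of each peak was covered by the other, 6 ZT22 peaks were shared, and with summits within 100 bp 21 were. Local background was over 2 times the lowest at 6 ZT22 peaks, and without these 28 of 30 were shared.

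**Figure D1:**
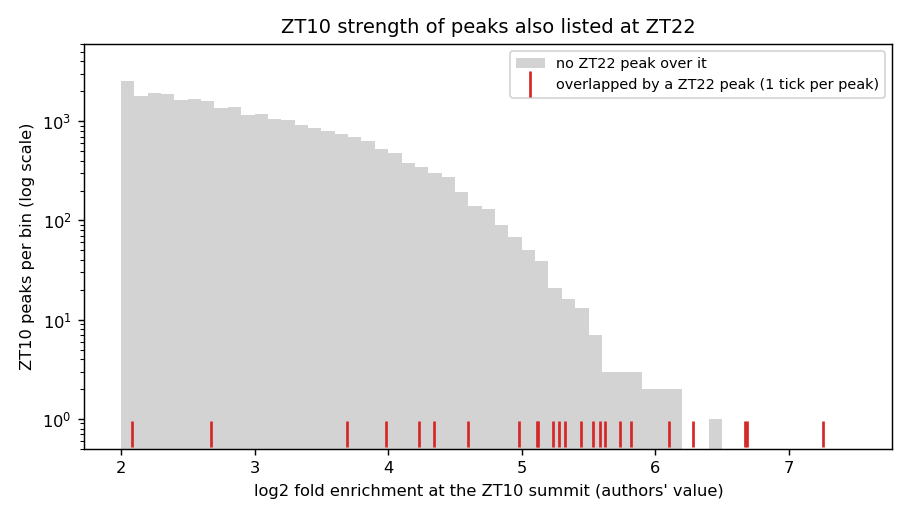
Number of ZT10 peaks (log scale) by log2 fold enrichment at the summit, in grey for peaks with no ZT22 peak over them, with a red tick for each of the 24 ZT10 peaks that a ZT22 peak overlapped. The ticks lie mostly at the strong end, with a mean of 5.14 against 2.92 for the grey peaks.

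Among the 15 strongest ZT10 peaks, 9 had no ZT22 peak over them. The strongest of these lay inside Arntl, the gene of the clock activator BMAL1, from 113204746 to 113211949 on chromosome 7, with a fold of 89.8 and its summit 29092 bp from the nearer end of the gene. The others lay in Gfod1 (71.0) and Arid3a (65.9), or outside protein-coding genes with Irs2, an adaptor of the insulin receptor (70.8 at 44599 bp and 62.7 at 111380 bp), Rpa1 (64.2 at 11149 bp), Rnase10 (60.8 at 9394 bp), Ust (56.9 at 117399 bp) or Cmtm7 (56.5 at 3596 bp) as the nearest, with the ZT10 fold in parentheses. Those with a ZT22 peak also included the sites nearest Nolc1 (68.9 at 14454 bp) and Pdcl3 (56.5 at 28141 bp).

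The next comparison asks which genes lay near ZT10 peaks. Core clock genes had REV-ERBα peaks almost without exception, with a summit within 10 kb of either end at 18 of 19 (94.7%, 95% interval 74.0 to 99.9). Across all protein-coding genes this was 51.4%, or 11118 of 21627 (Fisher's exact test, exact adjusted p = 0.000252). These include genes not active in liver, so whether a list, here or below, differs from other genes active in liver was not tested. The median of the strongest fold per gene was 14.9. For this and the other lists, values are of summits within that reach, and the strongest fold differed for 25 of 84 genes taken by the naming rule with a reach of 50 kb and for 17 of the 61 that still had a summit within 2 kb. After Npas2, the strongest such summits were at Nr1d1, the gene of REV-ERBα itself, with a fold of 35.9 at 89 bp from a gene end, and at Cry1 (27.7), which encodes a clock repressor. Bhlhe40 had a fold of 23.9, Clock 21.5 and Ciart 19.9. Others included Bhlhe41 (15.8), Per3 (15.3), Per2 (14.9), Nr1d2 (14.6), Per1 (11.8), Csnk1d (11.5), Rora (8.51), Cry2 (8.42), Btrc (4.83) and Csnk1e (4.81). Arntl was the member with no summit within 10 kb of an end of its annotated span. Its peak deeper in that span, with a fold of 89.8, was stronger than that at Npas2. Starts inside a span were not known here, so whether a peak deeper in a gene, here or below, lies at a promoter was not tested. Mean rank of the strongest fold was at percentile 84.5 of all genes (permutation adjusted p = 2.4e-05).

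Clock output factors had a summit at 10 of 10 genes (exact adjusted p = 0.00303, Fisher's exact test), led by Nfil3 (fold 42.6), Por (22.01) and Dbp (20.9), which encode a repressor, a P450 reductase and an activator. Corepressor complex genes had one at 10 of 10 (exact adjusted p = 0.00303, Fisher's exact test), with Tbl1xr1 (20.8) and Hdac3 (11.4) among the strongest, whose products act with REV-ERBα in repression. With a reach of 50 kb both stayed at 100%, a share at which a list of 10 could not pass (exact adjusted p = 0.0543 for each), and the other alternatives gave 0.00141 to 0.0137 and 0.00303 to 0.015. Hepatocyte transcription factors had one at 21 of 23 (exact adjusted p = 0.000252, Fisher's exact test), led by Bcl6 (32.9), Foxa2 (21.5) and Nr5a2 (18.3), while Nr3c1 and Nfia had summits only deeper inside the gene (strongest folds 15.5 and 26.2).

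Lists of lipid genes also had a ZT10 summit more often than other genes. Fatty acid and triglyceride synthesis had a summit at 19 of 22 genes (exact adjusted p = 0.0016 by Fisher's test, as for the lists below), with Pnpla3 (31.8), Scd1, a fatty acid desaturase (28.6), and Agpat2 (26.9) strongest. Scd2 had none, and Acaca and Lpin1 had summits only deeper inside the gene (strongest folds 13.5 and 19.4). Lipid droplets and lipoproteins had one at 20 of 22 (exact adjusted p = 0.000325), with Plin4 and Plin5 sharing a peak of fold 19.8 and Apoe at 19.2, none at Cidea and at Vldlr only 1 deeper inside the gene (6.12). Cholesterol synthesis had one at 23 of 24 (exact adjusted p = 2.58e-05), led by Insig2 (28.2), Srebf2 (23.5) and Hmgcs1 (14.5), with none at Nsdhl. Bile acid synthesis and transport had one at 15 of 16 (exact adjusted p = 0.00102), led by Nr0b2, a repressor of bile acid synthesis (36.4), the bile salt pump gene Abcb11 (31.2) and Abcc2 (20.9), while Slco1b2 had summits only deeper inside the gene (strongest fold 7.74). With a reach of 2 kb this list had 62.5% (exact adjusted p = 0.0912, against 4.93e-05 to 0.0105 under the other alternatives).

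Fatty acid oxidation and ketogenesis had a summit at 19 of 19 genes (exact adjusted p = 2.58e-05), with Ehhadh (27.9) and Pdk4 (25.9) among the strongest. Glucose and glycogen metabolism had one at 18 of 18 (exact adjusted p = 4.09e-05), led by Ppp1r3g (32.3), G6pc, the last enzyme of glucose production (29.4), and Ppp1r3b (21.97). Xenobiotic metabolism had one at 14 of 14 (exact adjusted p = 0.000325), led by the nuclear receptor genes Nr1i3 (21.7) and Nr1i2 (21.6) and by Cyp2e1 (21.5). The urea cycle and amino acid list had one at 18 of 19 (exact adjusted p = 0.000252), led by Hal (26.0), Ass1 (21.5) and Agxt (21.3), with none at Otc. Plasma proteins had one at 21 of 21 (exact adjusted p = 2.58e-05), led by Fgg (31.9), Itih1 (25.9) and Plg (24.4), and the mean rank of this list was the highest of the 24, at percentile 93.4. Autophagy had one at 12 of 12 (exact adjusted p = 0.00102), led by Map1lc3b (21.0), Gabarapl1 (16.9) and Atg14 (14.7). Heme synthesis and breakdown had one at 9 of 10 (exact adjusted p = 0.031), led by Cpox (22.01), Alad (15.8) and Uros (11.5), with none at Blvra. The heme call ended with length-matched random genes (permutation adjusted p = 0.0584) and with the nearest gene only (0.0843), could not pass at 100% with a reach of 50 kb (0.0543), and under the other alternatives had 0.00474 to 0.0347.

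Ribosomal protein genes, taken as broadly active promoters, had a summit at 20 of 20 (exact adjusted p = 2.58e-05) with a median strongest fold of 5.45, below the 6.81 of all ZT10 peaks. Rpl3 (9.01), Rpl10a (8.65) and Rpl7 (8.10) led the ribosomal list. Mean rank over all genes rises with the share of members that have a summit, so strength was also compared among genes with a summit only, a test chosen after seeing the data. Ribosomal protein genes then ranked below random lists, at percentile 28.7 (permutation adjusted p = 0.00154), where over all genes they stood at 63.4 (permutation adjusted p = 0.0346). Plasma proteins (87.1, permutation adjusted p = 4e-05), xenobiotic metabolism (85.9, 4e-05), bile acid synthesis and transport (84.3, 4e-05) and core clock genes (76.4, 0.00021) ranked above random lists. So did liver endothelial markers and the inflammation and acute phase list, which did not pass over all genes. Corepressor complexes (57.4, permutation adjusted p = 0.535), cholesterol synthesis (52.8, 0.715) and heme synthesis and breakdown (61.5, 0.336) did not pass.

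Markers of Kupffer, stellate and lymphoid cells and neuronal genes had a ZT10 summit less often than other genes. Kupffer cell markers had a summit at 3 of 14 (exact adjusted p = 0.0408), at Cd68 (8.0), Folr2 (6.38) and Csf1r (5.98). Stellate cell markers had one at 2 of 11 (exact adjusted p = 0.0408), at Pdgfrb (6.53) and Reln (4.02), and lymphocyte markers at 2 of 11 (exact adjusted p = 0.0408), at Cd4 (10.4) and Nkg7 (5.34). Neuronal genes had one at 2 of 19 (exact adjusted p = 0.000644), at Slc17a7 (6.17) and Eno2 (5.71). Lists that did not pass the test were liver endothelial markers at 5 of 13 (exact adjusted p = 0.431), led by Stab2 (24.3), Oit3 (15.3) and Dnase1l3 (13.7), cholangiocyte markers at 3 of 9 (exact adjusted p = 0.362; Sox9 10.4, Cdh1 6.44 and Spp1 5.25), photoreceptor genes at 4 of 12 (exact adjusted p = 0.292; Gnat1 16.9, Cnga1 9.57 and Sag 8.46), and inflammation and acute phase at 8 of 14 (exact adjusted p = 0.792), where Saa1 and Saa2 shared a peak of 26.5 and Socs3 had 19.9. All 4 calls of fewer peaks ended under at least 1 alternative: over the alternatives the exact or permutation adjusted p ran from 0.00325 to 0.21 for Kupffer, 0.0173 to 0.261 for stellate, 0.0137 to 1.0 for lymphocyte and 0.00048 to 0.0865 for neuronal genes. With a reach of 50 kb lymphocyte markers had a summit at 72.7%, and their direction turned.

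**Figure D2:**
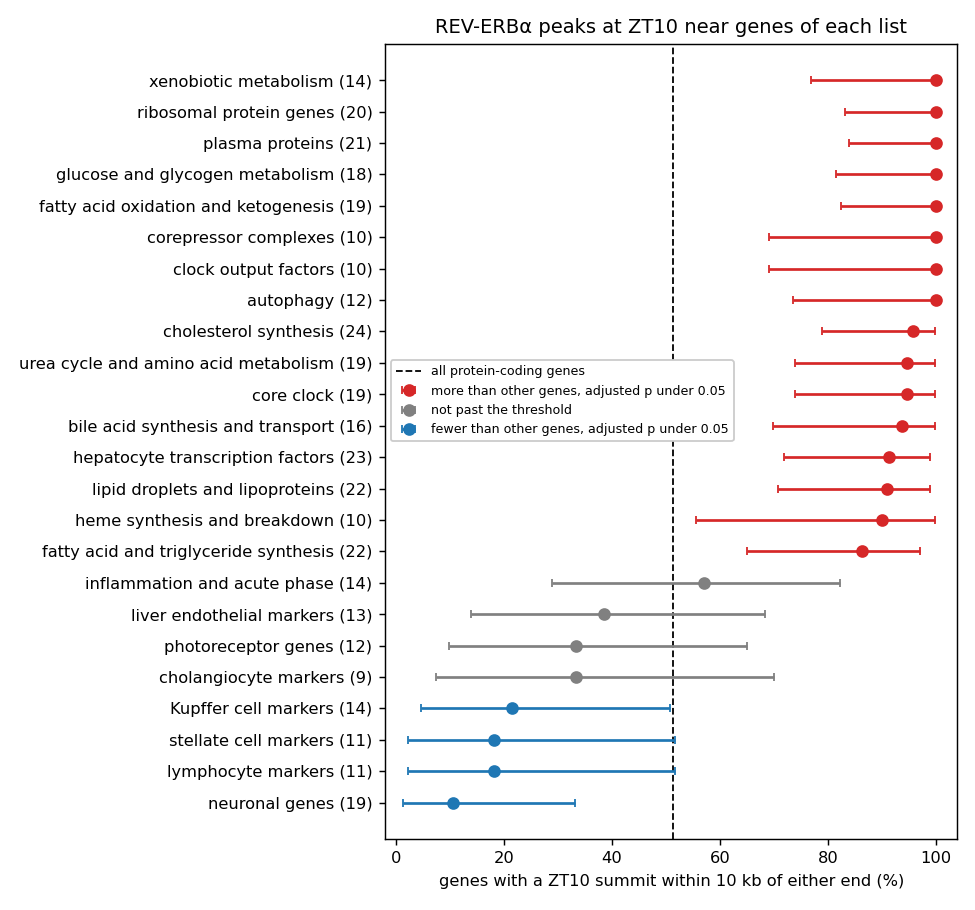
Share of the genes of each list (number of members in parentheses) with a ZT10 summit within 10 kb of either end, in percent, with 95% exact Clopper-Pearson intervals. The dashed line is the share over all protein-coding genes, 51.4%; 16 lists (red) lay above it and 4 (blue) below it past the threshold.

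The last comparison asks where ZT10 peaks lay relative to genes. Summits within 1 kb of a protein-coding gene end made up 23.3% (6502 of 27920 on chromosomes 1 to 19 and X), against 2.91% of random positions. A further 25.4% lay 1 to 10 kb away (17.8% of random positions), 31.0% lay 10 to 50 kb away (28.8%) and 20.3% lay farther than 50 kb (50.5%). Summits inside gene spans made up 59.4%, against 39.4% of random positions. Peaks within 1 kb of a gene end were weaker, with a mean log2 fold of 2.75 ± 0.58 (SD) against 2.97 ± 0.74 for the other 21418 (difference -0.22, permutation p = 1e-05, the smallest possible). Strand was not used here, so a gene end stands for its start or its finish.

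**Figure D3:**
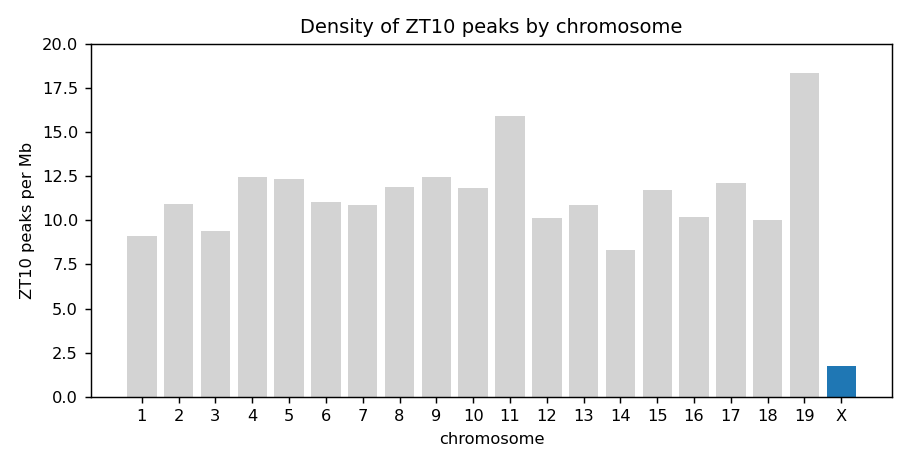
ZT10 peaks per Mb on each chromosome (bars). The X chromosome (blue) had 1.75 peaks per Mb, and the autosomes (grey) had 8.32 to 18.4.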

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

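Tests with length-matched genes, the gene span, no X chromosome, no ZT22 peaks of high background, a −log10 q limit on ZT22 peaks or genes with a summit only were chosen after seeing the data. No paired analysis was possible because the authors pooled the samples of each time into 1 list, and leaving out a replicate was not possible for the same reason. The motif alternatives and the one without repeats were not run. A −log10 q of at least 5 left every ZT10 peak and 1 row per interval removed none, so for results from the ZT10 list alone both say nothing of stability.

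The peak counts stayed within 1.5 times (21189 at ZT10 and 24 at ZT22 with a −log10 q of at least 10, 32 at ZT22 with at least 5). Shared ZT22 peaks numbered 6 with 50% of each peak covered, where wide ZT10 peaks hold narrow ZT22 ones, 18 of 24 with a −log10 q of at least 10 in both lists, since it removed shared ZT22 peaks only, 26 of 32 with at least 5 in both, and 21 to 30 otherwise. The strength difference of shared peaks kept its sign and side of the threshold throughout, at 1.63 to 2.41. Summits within 1 kb made up 28.7% with ends of all annotated genes. A pseudocount of 0 left 16.9% (ZT10) and 25% (ZT22) of summits whole. The worth of 1 fragment was kept from the fit with a pseudocount of 1, so these shares cannot decide between the pseudocounts. Lists with more peaks numbered 13 to 16. Lists of higher mean rank numbered 14 to 16, a count that partly restates presence except in the 14 among genes with a summit only.

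Fewer peaks were called for 2 lists at a reach of 2 kb, 1 at 50 kb, 1 with the nearest gene only, 2 with neighbours counted once and 2 with a −log10 q of at least 10, and weaker lists numbered 2 at 2 kb, 2 at 50 kb, 2 at a −log10 q of at least 10 and 1 among genes with a summit only, against 4. The share of members lost its call as follows. At 50 kb it was 100% for clock output factors, corepressors and heme, where a list of 10 had no way to pass, so this says nothing of stability, and it was 45.5% for stellate and 47.4% for neuronal genes. At 2 kb it was 62.5% for bile acids, 14.3% for Kupffer and 18.2% for stellate markers. With the nearest gene only it was 80.0% for heme, 27.3% for stellate, 27.3% for lymphocyte and 26.3% for neuronal genes. With neighbours counted once it was 25% for Kupffer and 20% for lymphocyte markers, with a −log10 q of at least 10 it was 21.4% and 18.2%, with length-matched genes 90.0% for heme, and without X 23.1% for Kupffer markers. Directions turned, without passing the threshold, for endothelial (61.5%) and cholangiocyte markers (55.6%) with the nearest gene only, and for lymphocyte (72.7%) and photoreceptor genes (75.0%) at 50 kb.

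Mean rank percentiles lost their call for heme at 50 kb (68.3), Kupffer (38.3) and stellate markers (38.3) at 2 kb, stellate (33.4) and lymphocyte markers (45.4) at 50 kb, Kupffer (37.5), lymphocyte (36.6) and ribosomal genes (56.9) with a −log10 q of at least 10, and ribosomal genes without X (61.9). They turned for endothelial markers at 2 kb (47.8), at 50 kb (49.6), with length-matched genes (50.4) and without X (49.7), and for photoreceptor genes at 50 kb (53.6). Among genes with a summit only, corepressors (57.4), cholesterol synthesis (52.8), heme (61.5), Kupffer (42.1), stellate (20.4), lymphocyte (47.1) and neuronal genes (31.8) lost their call, inflammation (79.5) and endothelial markers (84.7) gained one, ribosomal genes turned past the threshold (28.7) and photoreceptor genes turned without passing it (57.1). Beyond these the cause was not tested.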

Other observations

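The tests of gene families, depth, the limit on peaks, common loss, local background and the X chromosome were chosen after the result was seen, and that of neighbouring peaks before. Gene families, formed by the letters that open the symbol (102 families of at least 20 members), added to the lists of the report, and those named here were picked after their values were seen. By Fisher's exact test with adjustment over the families, 33 had more genes with a ZT10 summit within 10 kb than other genes and 25 had fewer. The Ugt family of glucuronosyltransferases had one at 20 of 22 genes (exact adjusted p = 0.000509), the Mup family of urinary proteins at 19 of 22 (exact adjusted p = 0.00265), the Cyp family of cytochromes P450 at 76 of 99 (exact adjusted p = 1.97e-06) and the Serpina family of protease inhibitors at 19 of 24 (exact adjusted p = 0.0147). Their median strongest folds were 13.4, 12.1, 10.5 and 11.1. A high share was not confined to these families. Abhd (20 of 20), Gtf (21 of 23), Sec (25 of 29), Cdc (27 of 32) and Vps (29 of 35) also passed, with shares above those of Cyp and Serpina. The median strongest folds of these were lower, at 8.03, 6.12, 7.01, 5.82 and 5.98. The Mrpl genes of the mitochondrial ribosome had a summit at 43 of 49 (exact adjusted p = 1.31e-06, median 6.72), and the Mrps genes of the same ribosome did not pass, with 19 of 29 (exact adjusted p = 0.191). All 20 ribosomal protein genes of the fixed list had a summit. Of genes whose symbols open with Rpl, 45 of 53 had one (exact adjusted p = 3.42e-06), and with Rps 34 of 44 (exact adjusted p = 0.00204). Opening letters can take in genes that do not encode ribosomal proteins, so these shares are not comparable with that of the fixed list. Receptors of smell had few, with 25 of 1110 Olfr genes (exact adjusted p = 8.43e-308) and 5 of 355 Vmn genes (exact adjusted p = 8.83e-101), as did keratins, with 7 of 53 Krt genes (exact adjusted p = 8.35e-08). Members of a family often lie side by side and can share a peak.

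The ZT22 list was far shorter than the ZT10 list. Lower depth at ZT22 was argued against by the relative depth of 0.97, if the same control served both pools. A stricter limit was argued against by the lowest fold kept, 4.08 at ZT22 and 4.01 at ZT10. A single factor of lost immunoprecipitation was tested at 15 shared peaks with the lowest background, summits within 100 bp and a pileup ratio under 0.5, a set chosen after the ratios of single peaks had been seen. The ZT22 excess over background was 0.055 (0.0421 to 0.0705, 95% counting interval) of the ZT10 excess near Nolc1, the lowest of the 15. The highest was 0.405 (0.311 to 0.521), at a Loxl4 peak from 42611308 to 42612941, and these intervals do not meet. That peak had folds of 12.9 at ZT10 and 5.83 at ZT22 and is not the strong Loxl4 site. A ZT10 peak this weak could be listed at ZT22 only with a high ratio. The strongest peak, nearest Il12b, had 0.372 (0.348 to 0.398), also above the Nolc1 interval. A loss of efficiency that adds to other differences stays open, as do differences between replicates, which the pooled lists hide, and the time of day itself, and anti-HA signal from untagged liver was not analysed here.

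Of the 36 ZT22 peaks, 9 had no ZT10 peak over them or a ZT22 pileup at least 0.5 times that at ZT10, with ratios above 1 nearest Zdhhc25 (1.23, 95% counting interval 1.095 to 1.386) and Wls (1.25, 1.17 to 1.34). Local background was over 2 times the lowest at 5 of these and at 1 of the other 27 (Fisher's exact test, two-sided, p = 0.00179). Some of the 27 lay under the same ZT10 peak, while the test treats them as independent. High local background is a candidate source of part of this pattern. The 5 of the 9 with high background lay nearest Gm525, Tmem196, Piezo2, Wls and Vmn2r129, with backgrounds 8.99 to 48.7 times the lowest. The remaining 4, among them those near Zdhhc25, Dop1b and Uaca, had 1.0 to 1.26 times the lowest and stay unexplained. All 9 were 200 to 336 bp wide, against a median of 862 bp for the others, and whether they lie in repeats was not tested.

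The X chromosome had 298 ZT10 peaks, or 1.75 per Mb, where the autosomes had 8.32 to 18.4. A single X copy alone was argued against, since after autosomal pileups were halved the lowest autosome still had 3.61 per Mb, above the interval of the X value (1.55 to 1.96). Fewer genes alone were too, with 0.308 peaks per gene on X (0.274 to 0.346) and 0.779 on the lowest autosome. Both together cannot be told apart from the data, and this rests on chromosome 7 alone. The X value of 0.308 lay below the lowest halved autosome, 0.317 on chromosome 7, by less than its counting error. It was far below the median of 0.66, and the next lowest, 0.426 on chromosome 2, lay above the X interval. The ZT10 list also held 9 peaks on the Y chromosome. The sex of the animals was not used here, and no biological explanation was tested.

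Neighbouring sites may share their strength. Between 11847 pairs of adjacent summits 5 to 25 kb apart, Pearson's r of log2 fold was 0.132 and Spearman's rho 0.116, and the highest r of 1000 permutations within chromosomes was 0.038. The correlation is across peaks, which are not independent replicates, and it is small.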
